A study of Homo sapiens with 3 samples.

How the data were processed

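Total RNA from U251 cells carrying a control shRNA, an shRNA against BMI1 or an shRNA against USP22 was measured on 1 array each, and the groups were taken from the labels. All 3 arrays lay on 1 slide and were read in 1 scan, so slide and scan do not differ between groups. Per the file headers, the scanner images were read with Agilent Feature Extraction 10.7.1.1, which the submitters' processing notes also name, from a one-colour Cy3 array annotated to hg19. The deposited spot intensity is, per the file headers, the background-subtracted and spatially detrended signal of each spot, with a surrogate value where the signal was not above background, and it is not normalized between arrays. The mean pixel intensity and the local background intensity of each spot are also deposited. A value table of the series holds log2 values deposited by the authors. Its columns have identical quartiles and a median of 5.09, so they appear quantile normalized between arrays. The steps and centring behind it are not given in the sources used here, and each column followed log2 of the matching array's processed intensity with r from 0.9997 to 0.9999. That table was used only as an alternative.

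Each array held 62976 spots, of which 58717 were not controls, for 50598 probes. Outlier-flagged spots were left out: 308 in the control, 298 in the BMI1 shRNA and 344 in the USP22 shRNA array. The log2 processed intensity was averaged over the spots of a probe, and the array's 75th percentile over non-control probes was subtracted. Those percentiles were intensities of 345, 311 and 319 in the control, BMI1 shRNA and USP22 shRNA arrays. A gene was represented by its probe with the highest mean over the arrays, and was measured in a comparison if that probe was well above background on at least 1 of the 2 arrays. Where the other array was not well above background, the difference was taken against the higher of that array's lowest well-above-background signal and the probe's own signal, and is printed as at least N-fold. Names came from the probe's accession through a RefSeq gene table of GRCh38 for 28173 probes, from the symbol for 2618 and from an older symbol for 620, while 19187 probes kept the name in the file. Positions are those of the files on hg19.

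With 1 array per group no test across samples exists, and the number of arrays limits the precision. The error printed is that of replicate spots. It came from the 10 spots of a probe printed 10 times, and for other probes from the pooled spot SD of the 687 such probes that were well above background on all arrays, at the same intensity. The spot SD in the dimmest of 10 intensity bins was 0.40 to 0.60 (log2), against 0.04 to 0.05 in the brightest. Multiple probes of a gene could disagree: of 147 genes with several measured probes that were at least 2-fold apart with BMI1 shRNA, 59 had probes in both directions, and with USP22 shRNA 65 of 355.

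Before the data were examined, 24 gene lists and the rules for named genes were fixed. The lists covered PRC1, PRC2 and SAGA subunits, CDK inhibitors, p53 targets, HOX genes, other developmental transcription factors, glioma stem, neuronal, astrocyte and oligodendrocyte genes, and G1/S and G2/M genes. They also covered interferon, NF-kB, ATF4 and ER stress, matrix, Notch, Wnt, receptor kinase, hypoxia and cholesterol genes, markers of other cell types, and reference genes. A list's median was placed among 10000 random lists of the same size of protein-coding genes matched on mean expression in 20 bins, and it stands apart below percentile 2.5 or above 97.5. This describes these arrays and is no p-value. Random lists would put 1.2 of the 24 lists apart in each comparison. Named genes were the targets, the 10 highest and 10 lowest against control for each shRNA and for both together, the 5 highest and 5 lowest in the direct comparison, and up to 4 members of each list at least 2-fold from control, or up to 2 where none was. The ranked genes had to have a gene symbol, a brighter array at or above the median signal of detected probes, and no detected probe in the other direction.

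Alternatives were normexp background correction (offset 50) on mean and background intensities, a median in place of the 75th percentile, quantile normalization, cyclic loess, the authors' value table, probes well above background on all 3 arrays, no filter, the mean of a gene's probes, measured differences in place of bounds, thresholds of 1.5-fold and 3-fold, and 10 bins. A restriction to genes at or above the median signal was added after the counts were seen. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and, for normexp, quantile and loess, limma 3.58.1 in R 4.3.3. Plots used matplotlib 3.10.9. The counting was tested for BMI1 shRNA against control on arrays simulated from the control array, all with that array's spot noise, with 23444 genes measured. Of 50 genes simulated 3-fold higher, 92% came out at least 2-fold higher, and of 50 simulated 1.5-fold higher, 6% did. For lists of 25 unchanged simulated genes, 5% of 200 stood apart.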

Results

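Gene expression was measured in U251, an established human glioblastoma cell line, after stable lentiviral transduction with a short hairpin RNA (shRNA) against BMI1, an shRNA against USP22 or a control shRNA. BMI1 is a ring finger subunit of Polycomb repressive complex 1 (PRC1), and USP22 is the deubiquitinating enzyme of the SAGA coactivator complex. Total RNA of each culture was labelled with Cy3 and hybridised to 1 one-colour array, so each group holds 1 array and there are no replicates. Differences between arrays are therefore described by size, without a test, and the value after each ± is the error between replicate spots of a probe, which leaves out the spread between cultures. Of 50598 probes, 58.3% were well above background in the control array, 59.0% in the BMI1 shRNA array and 60.3% in the USP22 shRNA array. No spot was saturated.

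The targeted genes were measured first. BMI1 signal in the BMI1 shRNA array was 35.6% of that in the control array at the probe on chromosome 10 from 22619577 to 22619636 (hg19), a log2 difference of -1.49 ± 0.09. A probe for BMI1 at 22617587 to 22617995 on the same chromosome gave 38.6% of control, or -1.38 ± 0.09. USP22 signal in the USP22 shRNA array was 23.4% of control at its probe on chromosome 17 from 20903562 to 20903621, a log2 difference of -2.09 ± 0.06. The gene that was not targeted lay near the control level. The BMI1 probes differed from control by 0.06 ± 0.08 and -0.01 ± 0.08 in the USP22 shRNA array, and the USP22 probe by 0.03 ± 0.06 in the BMI1 shRNA array. Both arrays thus carried a lower level of the transcript named in their label. Exon and UTR annotation of hg19 was not used here.

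**Figure D1:**
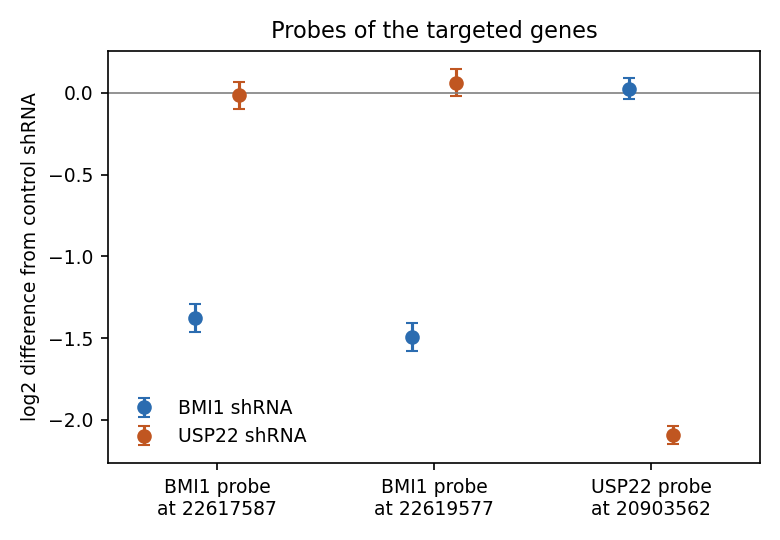
Log2 difference from the control shRNA array (y axis) for each probe of BMI1 and USP22 (x axis, with the hg19 start of the probe), with bars of 1 spot error; there is 1 array per group. The BMI1 probes sit at -1.49 and -1.38 in the BMI1 shRNA array, and the USP22 probe at -2.09 in the USP22 shRNA array.

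The comparison of BMI1 shRNA with control asked which transcripts differ when BMI1 is reduced. Interferon-stimulated genes, which carry the antiviral response, were lower as a group. All 32 measured members were below control, 16 of them by at least 2-fold, with a median log2 difference of -1.004. IFITM1, a membrane protein that restricts viral entry, was lower by -2.73 ± 0.07, and MX1, an antiviral GTPase, by -2.49 ± 0.07. RSAD2 was lower by -2.09 ± 0.14, and OAS1, which makes the 2'-5' oligoadenylates that activate RNase L, by -1.88 ± 0.14. The list's median lay below all 10000 random lists of genes matched on expression.

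Cholesterol synthesis genes were lower in 18 of 19 measured members, with a median of -0.29 at percentile 0. INSIG1, a sterol-regulated brake on SREBP processing, was the 1 member at least 2-fold lower, at -1.05 ± 0.08. Hypoxia genes had a median of -0.15 at percentile 0, with members on both sides. CA9, a carbonic anhydrase induced by low oxygen, was lower by -2.26 ± 0.14, while ANGPTL4, a secreted inhibitor of lipoprotein lipase, was higher by 3.25 ± 0.14. Notch pathway genes had a median of -0.28 at percentile 0.07. Their members at least 2-fold lower were HES5 (at least 2.23-fold) and JAG2 (at least 2.005-fold), both bounds from dim probes. Astrocyte genes had a median of -0.25 at percentile 0.34. GFAP, the astrocytic intermediate filament, was lower by -1.10 ± 0.14, and S100B was at least 2.58-fold lower. With probes well above background on all 3 arrays this list came inside the random range, at percentile 2.92.

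HOX genes, classical Polycomb targets, had a median of -0.11 at percentile 0.67. HOXA2, at -1.43 ± 0.35, was the 1 of 33 measured members that reached 2-fold. Glioma stem and neural progenitor genes had a median of -0.09 at percentile 1.70. PDGFRA, a growth factor receptor of glial progenitors, was lower by -1.39 ± 0.08, and L1CAM was at least 3.06-fold lower. This list came inside the random range in 6 of 10 alternatives: with no filter on dim probes its median was 0.02 at percentile 12.1, and with normexp background correction -0.04 at percentile 10.1.

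Another 3 lists lay on the higher side. NF-kB and cytokine genes had a median of 0.36 at percentile 100, with 18 of 22 measured members above control. CXCL8, a neutrophil chemokine, was higher by 1.37 ± 0.08 (0.86 at another probe) and CSF2, a myeloid growth factor, by 1.14 ± 0.35. ATF4 and ER stress genes had a median of 0.21 at percentile 100. DDIT4, an inhibitor of mTORC1 signalling, went against that list at -1.30 ± 0.02. G1/S and replication genes had a median of 0.12 at percentile 98.1, and this list came inside the range of random lists with normexp (percentile 97.1), the mean of a gene's probes (80.2), genes at or above the median signal (92.4) and, at the bound itself, the authors' value table. MCM6, a subunit of the replicative helicase, was higher by 0.50 ± 0.06, while PCNA, the polymerase clamp, was lower by -0.67 ± 0.06.

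The other 14 of the 24 lists lay inside the range of random lists in the BMI1 shRNA array. Their median log2 differences were 0.04 for PRC1 subunits, 0.02 for PRC2 subunits, -0.003 for SAGA subunits, 0.13 for CDK inhibitors, -0.02 for p53 targets and 0.01 for other developmental transcription factors. They were -0.12 for neuronal genes, which stood apart with no filter on dim probes (percentile 1.11), -0.01 for oligodendrocyte lineage genes, 0.02 for G2/M genes, 0.02 for extracellular matrix and mesenchymal genes, and 0.12 for Wnt target genes. Receptor tyrosine kinases and growth factors had a median of 0.01, endothelial, immune and epithelial markers 0.05, and common reference genes 0.06. The CDK inhibitor CDKN2A was higher by 0.53 ± 0.14, under 2-fold, at the 1 of its 2 probes that was well above background on both arrays. The mean lay on the other side of 0 from the median for SAGA subunits (0.05), p53 targets (0.04), oligodendrocyte lineage genes (0.15), extracellular matrix and mesenchymal genes (-0.03) and Wnt target genes (-0.13).

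Of 23736 genes well above background in the BMI1 shRNA or the control array, 1090 were at least 2-fold higher and 1017 at least 2-fold lower with BMI1 shRNA. For 562 and 440 of these the dimmer array was not well above background, so the fold is a bound. Protein-coding genes made up 378 of the 1090 higher (34.7%) and 421 of the 1017 lower (41.4%), against 14805 of the 23736 measured. Among genes with a signal at or above the median of detected probes, a restriction added after the counts were seen, 127 were higher and 147 lower, and normexp gave 169 and 198. In arrays simulated without change, all with the spot error of the control array, 1.70% of 23247 genes came out at least 2-fold apart. The spot SD in the dimmest bin was 0.60 in the BMI1 shRNA array and 0.40 in the control array. The simulated share may therefore be too low for this comparison.

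Several of the genes farthest from control in the BMI1 shRNA array rested on 1 spot per array. For the higher genes named next, that spot was bright only in the BMI1 shRNA array. RGS11, a regulator of G protein signalling, was higher by 3.84 ± 0.35, LRG1 by 3.28 ± 0.35 and the Hippo kinase LATS1 by 2.78 ± 0.35, although another LATS1 probe gave 0.315. HTR5A-AS1 was at least 34.5-fold, CC2D2B at least 25.3-fold and TDRD6 at least 20.03-fold higher. WDR11-DT was higher by 4.32 ± 0.73, ZNF594-DT by 3.21 ± 0.35 and CREG2 by 2.53 ± 0.35. On the lower side, POT1, a subunit of the telomere-binding shelterin complex, was at -2.54 ± 0.07 and the calcium-binding protein S100A5 at -2.73 ± 0.09. MMRN2 was at -3.06 ± 0.35 and SLC45A2 at -2.63 ± 0.35, while UBTFL1 and the potassium channel KCNQ1 were at least 18.4-fold and 18.3-fold lower. UBTFL1 and KCNQ1 had intensities of 2.935 and 2.879 in the BMI1 shRNA array. They had 229.1 and 228.3 in the control array, and 185.7 and 200 in the USP22 shRNA array. An aberrant spot in the BMI1 shRNA array could give values such as those in this paragraph, and the error printed cannot show it.

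The comparison of USP22 shRNA with control asked the same of reduced USP22. Here interferon-stimulated genes were higher as a group. All 34 measured members were above control, 29 by at least 2-fold, with a median log2 difference of 1.97 at percentile 100. IFITM1 was higher by 4.32 ± 0.06, RSAD2 by 3.94 ± 0.12, OASL by 3.50 ± 0.08 and IFIT3 by 3.00 ± 0.07. NF-kB and cytokine genes had a median of 2.14 at percentile 100, with 20 of 23 measured members at least 2-fold higher. CSF2 was higher by 4.61 ± 0.31, the adhesion molecule ICAM1 by 4.37 ± 0.11 and TNF by 3.95 ± 0.31, and the cytokine IL1A was at least 12.1-fold higher.

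Stress and hypoxia genes were higher as well. ATF4 and ER stress genes had a median of 0.75 at percentile 100, and 7 of 21 members were at least 2-fold higher. DDIT4 was higher by 2.21 ± 0.01, the stress transcription factor ATF3 by 2.11 ± 0.06 and PPP1R15A, a phosphatase subunit that restores translation, by 1.35 ± 0.07. The 4 probes of ATF3 ranged from 0.12 to 2.22. Hypoxia genes had a median of 0.71 at percentile 100, with 10 of 26 members at least 2-fold higher. ANGPTL4 was higher by 3.78 ± 0.12, NDRG1 by 2.24 ± 0.06, ADM, which encodes adrenomedullin, by 1.85 ± 0.03, and ANKRD37 by 1.62 ± 0.07.

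Receptor tyrosine kinases and growth factors had a median of 0.32 at percentile 99.7, with 8 members at least 2-fold higher and 3 lower of 29. The growth factors FGF1, PDGFB and HBEGF were higher by 4.16 ± 0.12, 2.44 ± 0.31 and 2.21 ± 0.08, although another FGF1 probe gave 0.003. PDGFRA was lower by -2.08 ± 0.07. Extracellular matrix and mesenchymal genes had a median of 0.22 at percentile 99.7, with 9 higher and 1 lower by at least 2-fold of 40. CCN1, a matricellular protein, was higher by 1.98 ± 0.06, and the dim probes of COL6A3 and FN1 gave 2.29 ± 0.58 and 1.996 ± 0.58. POSTN, which encodes periostin, was at least 5.87-fold lower. With normexp this list moved just inside the random range, at percentile 97.4. G1/S and replication genes had a median of -0.18 at percentile 1.76. The cell cycle transcription factors E2F1 and E2F2 were lower by -1.11 ± 0.01 and -1.04 ± 0.06. That list came inside the random range with normexp (percentile 2.84) and with the mean of a gene's probes (3.63).

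The remaining 17 lists lay inside the random range in the USP22 shRNA array, and some held members far from control in both directions. Glioma stem and neural progenitor genes had a median of 0.03 and a mean of -0.31, with 5 members at least 2-fold lower and 1 higher, MSI2 at 1.34 ± 0.06, named after its values were seen. The neural stem cell transcription factors SOX2 and POU3F2 were at -1.39 ± 0.06 and -1.35 ± 0.06, and the fatty acid binding protein FABP7 of radial glia was at -2.02 ± 0.07. Neuronal genes had a median of -0.002. GAP43 was at -2.29 ± 0.31 and the neurofilament NEFL at -1.86 ± 0.06, while GAD1, a GABA-synthesising enzyme, was at 1.98 ± 0.08 (0.96 at another probe). NCAM1 was at -1.90 ± 0.07, with its 3 probes between -1.90 and 0.45. Astrocyte genes had a median of -0.28, with GFAP at -2.24 ± 0.12 and NDRG2 at -1.14 ± 0.07 (-0.39 at another probe). The p53 targets had a median of 0.05, with the apoptosis gene BBC3 at 1.79 ± 0.07, CDKN1A at 1.71 ± 0.31 and CCNG1 at -1.28 ± 0.07. That list stood apart with the mean of a gene's probes (percentile 97.6) and among genes at or above the median signal (99.0).

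Among chromatin complexes, PRC2 subunits had a median of 0.28 at percentile 96.5, with MTF2 at 0.68 ± 0.06 and EZH1 at 0.66 ± 0.08. PRC1 subunits had a median of 0.06, with SCML2 at 1.67 ± 0.31. SAGA subunits had a median of -0.12. TAF10, which is also part of TFIID, was at -1.02 ± 0.06 and USP27X, a deubiquitinase related to USP22, at -1.49 ± 0.31. HOX genes had a median of -0.02 and a mean of 0.10, with HOXB2 at 2.46 ± 0.31 (0.47 at another probe) and HOXD8 at -1.42 ± 0.12. Other developmental transcription factors had a median of 0.06, with POU4F1 at 2.84 ± 0.31 and LHX1 at 1.97 ± 0.06.

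The medians of the other lists were 0.24 for CDK inhibitors, which stood apart with probes well above background on all 3 arrays (0.56, percentile 98.1), 0.04 for oligodendrocyte lineage genes, 0.08 for G2/M genes, 0.03 for Notch pathway genes and 0.16 for cholesterol synthesis genes. They were -0.10 for Wnt target genes with a mean of 0.08, 0.004 for endothelial, immune and epithelial markers with a mean of -0.02, and -0.08 for common reference genes with a mean of 0.11. Of the reference genes, the MHC class I light chain B2M was at 1.26 ± 0.02 and the transferrin receptor TFRC at 1.11 ± 0.03. The macrophage marker CD68 was at -1.26 ± 0.12.

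**Figure D2:**
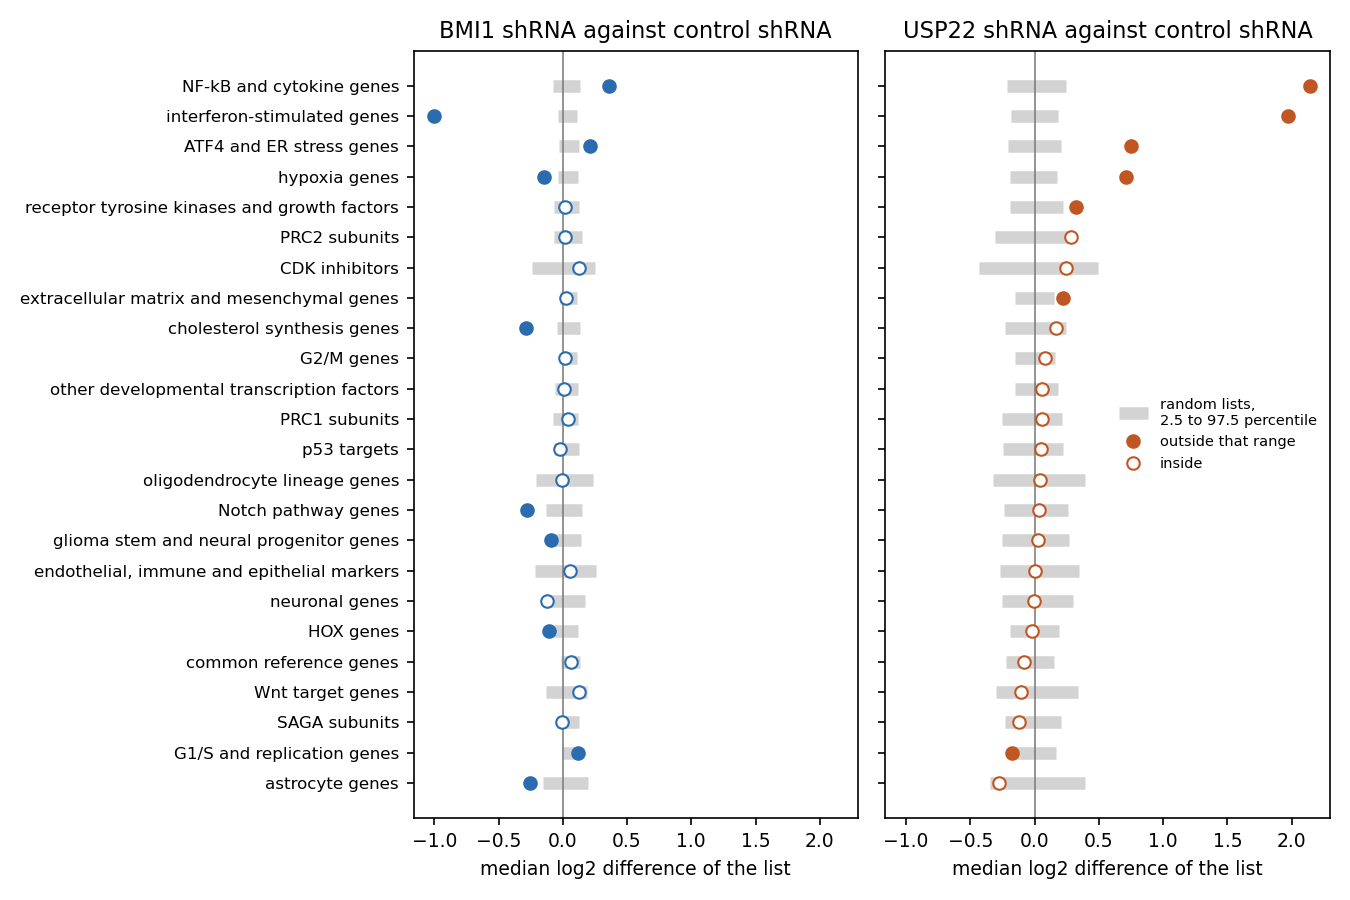
Median log2 difference from the control shRNA array (x axis) of each of the 24 gene lists (y axis), for BMI1 shRNA (left) and USP22 shRNA (right); grey bars span the range in which a list does not stand apart from random lists matched on expression, and filled points lie outside it. Interferon-stimulated genes sit at -1.004 on the left and at 1.97 on the right.

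Of 23712 genes measured, 1342 were at least 2-fold higher and 872 at least 2-fold lower with USP22 shRNA, of which 400 and 168 are bounds. Among genes at or above the median signal the counts were 649 and 423, and normexp gave 605 and 367. Protein-coding genes made up 867 of the 1342 higher (64.6%) and 555 of the 872 lower (63.6%), against 14827 of the 23712 measured. Of the ranked genes, the smooth muscle actin ACTG2 was at 6.08 ± 0.08. ANXA3, a calcium-dependent phospholipid-binding protein, was at least 39.7-fold higher. The stress-induced gene IER3 was at 4.35 ± 0.06, the proteoglycan SRGN at 4.30 ± 0.31 and the interferon-inducible GTPase GBP5 at 3.995 ± 0.07. On the lower side, the long noncoding RNA SOX2-OT, which overlaps SOX2, was at -3.18 ± 0.08 and the cannabinoid receptor CNR1 at -3.03 ± 0.06. CYFIP2 was at -2.76 ± 0.31 (-0.99 at another probe), the imprinted gene MEST at -2.47 ± 0.06 and ZNF664 at -2.37 ± 0.06, and GYPB was at least 19.3-fold lower.

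Both comparisons use the same control array, so their differences share its error. Genes higher in both knockdown arrays included ANGPTL4, XDH, which encodes xanthine dehydrogenase (2.14 ± 0.14 with BMI1 shRNA and 3.52 ± 0.12 with USP22 shRNA), and the semaphorin SEMA7A (1.61 ± 0.03 and 2.42 ± 0.03). The transcription factor KLF2 was at 1.56 ± 0.03 and 1.93 ± 0.02, the pseudokinase TRIB1 at 1.30 ± 0.07 and 1.45 ± 0.06, and the MAP kinase phosphatase DUSP5 at 1.19 ± 0.14 and 2.77 ± 0.12. CHST4, CXCL8, TMEM200A and FGF5 were the rest of the 10 highest in both. Genes lower in both included CNR1 (-1.48 ± 0.07 and -3.03 ± 0.06), PDGFRA, the neuropeptide Y receptor NPY1R (-1.38 ± 0.09 and -2.49 ± 0.08) and SOX21 (-1.35 ± 0.14 and -2.23 ± 0.12). The keratin KRT15 was at -1.47 ± 0.08 and -1.47 ± 0.07, CNTF at -1.97 ± 0.35 and -1.85 ± 0.31, and RPRM at -1.49 ± 0.14 and -1.92 ± 0.12. RAB3C was at -5.04 ± 0.73 and -5.07 ± 0.58. FAM9A was at least 34.8-fold and 30.6-fold lower, and RIMBP2 was at -3.60 ± 0.73 and at least 17.6-fold lower. RAB3C, FAM9A and RIMBP2 were each read from 1 spot per array. That spot was bright only in the control array (intensities of 558, 433 and 250, and at most 18.5 in the knockdown arrays). An aberrant control spot would give such values, and the error printed cannot show it.

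Across the 20442 genes well above background on all 3 arrays, the differences of the 2 comparisons had a Pearson r of 0.21 and a Spearman rho of 0.26; genes are not independent replicates. Simulated unchanged arrays that share a control gave r of 0.50 with noise from replicate spots. Equal noise in the 3 arrays gives that value whatever its size, so it sets no level for the observed r. The covariance was 0.055, beside 0.061 in arrays simulated from replicate spots and 0.162 with noise from the spread of the 3 arrays. That spread includes any differences made by the shRNAs, so 0.162 sets no level for unchanged arrays. At least 2-fold higher in both were 64 genes and lower in both 63, against 21.2 and 18.7 for independent lists and 87.8 and 89.1 in the simulation from replicate spots. In opposite directions 35 genes were at least 2-fold from control, against 40.9 for independent lists and 2.22 in that simulation. Over all 22717 genes measured in both comparisons, bounds included, 117 were higher in both and 201 lower in both, against 33.1 and 39.0 for independent lists. A gene well above background only in the control array gets a bound below control in both comparisons. One well above background only in 1 knockdown array is not measured in the other comparison. The count of 201 was thus partly set by the rule for bounds, and 39.0 sets no level for it. There 36 were lower with BMI1 shRNA and higher with USP22 shRNA, and 9 the reverse. Part or all of the overlap may come from the shared control, which cannot be split. With no filter on dim probes r was 0.35.

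**Figure D3:**
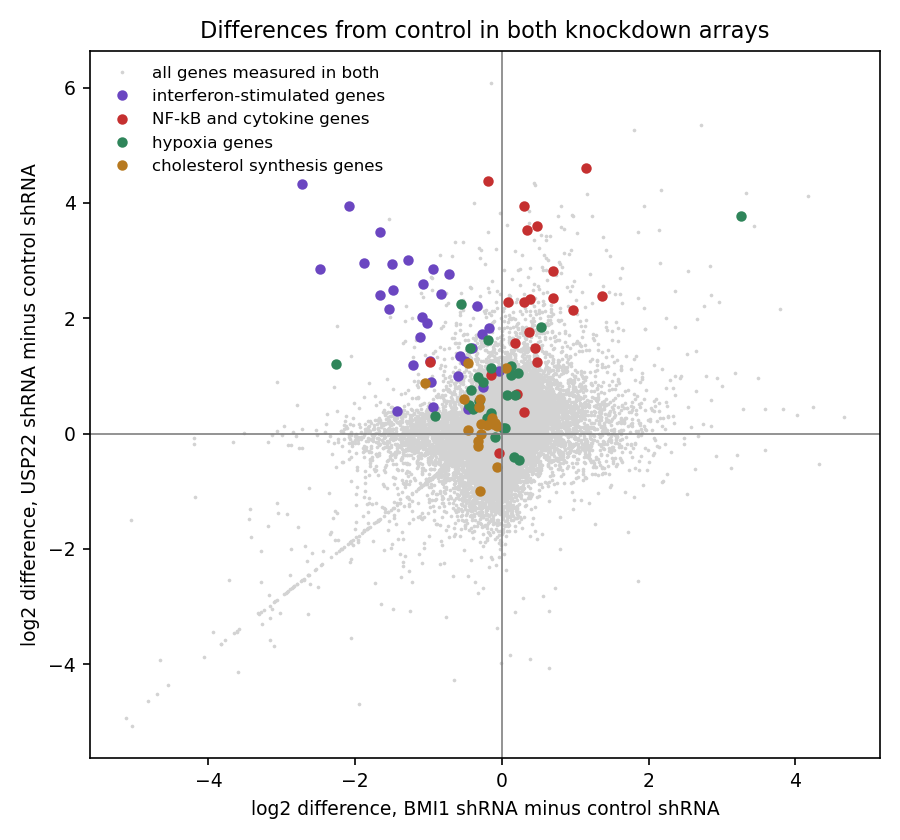
Log2 difference from control in the BMI1 shRNA array (x axis) and the USP22 shRNA array (y axis) for each gene measured in both, with members of 4 lists in colour; points along the lower left diagonal include genes dim in both knockdown arrays, whose values are bounds. Interferon-stimulated genes lie in the upper left, such as IFITM1 at -2.73 and 4.32.

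The direct comparison of USP22 shRNA with BMI1 shRNA does not use the control array. Of the ranked genes IFITM1 was higher by 7.05 ± 0.06 with USP22 shRNA, as were ACTG2 (6.22 ± 0.08), RSAD2 (6.03 ± 0.13) and MX1 (5.33 ± 0.06). ANXA3 was at least 38.7-fold higher. Lowest were HTR5A-AS1, WDR11-DT, CC2D2B, TDRD6 and ZNF594-DT, each of which was brightest in the BMI1 shRNA array and dim in the others. Each was read from 1 spot per array, so an aberrant spot in the BMI1 shRNA array could give these values too. Of 24224 genes measured, 1877 were at least 2-fold higher and 1394 at least 2-fold lower with USP22 shRNA. At or above the median signal the counts were 657 and 464. Of the 1877 and 1394 genes, 1024 and 680 were protein-coding.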

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

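The tests of the interferon pattern below were chosen after its values were seen; those of dim probes and of genes shared by both knockdown arrays were fixed before their result. Each result here lay on opposite sides of the control in the 2 knockdown arrays, and the difference was not tested, since each group holds 1 array. Among named genes, the log2 difference of USP22 shRNA minus BMI1 shRNA was 7.05 for IFITM1, 6.03 for RSAD2, 5.33 for MX1, 5.16 for OASL, 4.83 for OAS1 and 4.29 for IFIT3, all interferon-stimulated. It was 3.52 for DDIT4, 3.45 for CA9 and -3.58 for CREG2. CREG2 was at 2.53 with BMI1 shRNA and -1.05 with USP22 shRNA, on 1 spot per array that was bright only with BMI1 shRNA. Over lists, the median of that difference was 2.67 for interferon-stimulated genes, 0.89 for hypoxia genes and -0.33 for G1/S and replication genes.

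Interferon-stimulated genes were lower with BMI1 shRNA and higher with USP22 shRNA. A response common to both targeting shRNAs would by itself raise the list in both arrays, and its median with BMI1 shRNA was -1.004. That value is part of the pattern that raised the question, so it is no separate test. The state of the shared control array alone would move both comparisons one way, so it cannot give both signs. Without the control array, 33 of 34 members were at least 2-fold higher with USP22 than with BMI1 shRNA, with a median of 2.67. A higher level in the single control culture could still lie behind the median of -1.004 with BMI1 shRNA, which 1 control array cannot settle. Background correction, scaling and probe choice did not account for the opposite signs. Over 10 alternatives the median stayed at -0.90 or below with BMI1 shRNA and at 1.67 or above with USP22 shRNA. A response to the sequence of one shRNA, such as double-stranded RNA sensing, or a difference between single cultures cannot be told apart from an effect of reduced USP22 behind the median of 1.97, as there is 1 shRNA and 1 array per gene; all of these may contribute.

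Dim probes at least 2-fold from control may reflect the error of single spots. The shares given next use measured differences, not the bounds behind the counts of genes. Over all genes, measured differences gave 1491 higher and 1394 lower with BMI1 shRNA, against 1090 and 1017 with bounds. Over the 153 dim probes printed on 10 spots, 15.3% were at least 2-fold from control with BMI1 shRNA when 1 spot per array was drawn, and 3.92% (6 probes) when the 10 spots were averaged, a ratio of 0.257. Single-spot error is thus a candidate source of most 2-fold differences at dim probes in the BMI1 shRNA array. The test does not reach the ranked genes of that array, whose differences were much larger than 2-fold. HTR5A-AS1, for example, had an intensity of 378 in the BMI1 shRNA array and 7.57 in the control array. With USP22 shRNA the shares were 25.4% and 18.5% (30 of 162 probes), a ratio of 0.73 with 0.625 to 0.883 over draws, which lies between the bounds set in advance and leaves the part of spot error open. An effect of the knockdowns on dim genes was not tested apart from this.

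Genes moved the same way in both knockdown arrays could come from the control they share. Over the 8158 genes with a mean level above 1, the covariance of the comparisons was 10.6 times the spot-error variance of the control array (0.0246 against 0.00233). That comparison sets single samples against technical noise, so although it passed the bound set in advance it excludes nothing about the control culture. At that level 15 genes were at least 2-fold from control in the same direction in both, 8 higher and 7 lower, against 0.721 and 0.913 for independent lists. In opposite directions there were 13 against 1.73, so the excess was not specific to one direction. Simulated arrays sharing a control gave 0 in the same direction with noise from replicate spots. With noise from the spread of the 3 arrays they gave 42.7. That spread includes any differences made by the shRNAs, so 42.7 sets no level for unchanged arrays. The state of the single control culture and an effect common to both knockdowns cannot be told apart for these genes, because there is 1 control array.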

How the results depend on the processing

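The restriction to genes at or above the median signal, and that of r to genes with a mean level above 1, were chosen after seeing the data. All other alternatives were set beforehand. The covariance test above, at a mean level above 1, is separate from these and was fixed before its own result. Named differences of at least 2-fold had the same direction in 1271 of 1271 gene and setting pairs, and 1217 stayed at least 2-fold. Pairs without a value in the alternative setting were left out, so genes that a stricter filter removed do not count as lost. The ranked genes were picked for large differences and all settings use the same spots, so this agreement was likely in advance. Of 480 list medians under alternatives, 462 stayed on the same side of the percentile bounds, 14 came inside them and 4 went outside. Among lists that stood apart 1 median changed sign, as it came inside: glioma stem and neural progenitor genes with BMI1 shRNA, at 0.018 with no filter on dim probes. Another 47 changes of sign were in lists inside the bounds. BMI1 in the BMI1 shRNA array was at -1.35 with normexp, and r between the comparisons was 0.35 with no filter on dim probes; the cause was not tested.

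Counts at least 2-fold apart are given next as higher and lower, for BMI1 shRNA, USP22 shRNA and USP22 against BMI1 shRNA in that order. With normexp they were 169 and 198, 605 and 367, and 607 and 379. With no filter on dim probes, which adds genes, they were 3309 and 2179, 3143 and 1951, and 3396 and 3307. With probes well above background on all 3 arrays, which removes genes, they were 480 and 567 for BMI1 shRNA and 1236 and 922 for USP22 against BMI1 shRNA. Among genes at or above the median signal they were 127 and 147, 649 and 423, and 657 and 464. The 1.5-fold threshold gave 2393 and 2112, 3193 and 2651, and 3920 and 3739. The 3-fold threshold gave 402 and 363, 553 and 221, and 737 and 449. The other scalings, the mean of a gene's probes and the measured difference in place of the bound kept all 6 counts within 1.5 times. The spot SD was largest at dim probes, so spot error may enter these counts. Its part was left open for USP22 shRNA and was not tested for USP22 against BMI1 shRNA. No paired analysis was possible because each group holds 1 array.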

Other observations

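The 4 gene lists in this part were chosen after the main results were seen, and their tests were fixed before their own values were; each was placed among random lists as in the report. MHC class I presentation genes, which process and display peptides to T cells, were higher in 15 of 16 members with USP22 shRNA, 7 by at least 2-fold, and lower in 15 of 16 with BMI1 shRNA, 0 by 2-fold. Their medians were 0.81 and -0.28. With USP22 shRNA the immunoproteasome subunit PSMB9 was at 2.15, the peptide transporter TAP1 at 1.997, HLA-B at 1.58 and HLA-C at 1.45, while PSMB10 was at -0.54. With BMI1 shRNA the class I transactivator NLRC5 was at -0.87 and PSMB9 at -0.54. Contractile and SRF target genes were higher in 13 of 14 members with USP22 shRNA, with a median of 0.88, and TAGLN, an actin-binding protein of smooth muscle, was at 3.44. With BMI1 shRNA their median was 0.10 at percentile 87.1.

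Immediate early and ERK feedback genes had medians of 0.52 with BMI1 shRNA and 0.97 with USP22 shRNA. With BMI1 shRNA 13 of 15 members were above control, 4 by at least 2-fold, and EGR2 at -0.26 and JUNB at -0.20 were below; with USP22 shRNA all 15 were above, 7 by at least 2-fold. Among the members at least 2-fold higher in both, FOS was at 1.25 and 1.62, the MAP kinase phosphatase DUSP6 at 1.06 and 1.54, and the feedback inhibitor SPRY4 at 1.08 and 1.04. Respiratory chain complex I genes were below control in 26 of 30 members with USP22 shRNA, none by 2-fold, with a median of -0.16.

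The hypotheses were as follows. MHC class I presentation genes may move with the interferon-stimulated genes: the list stood at percentile 0 with BMI1 shRNA and 100 with USP22 shRNA, as that predicts. It was chosen after the interferon result and read from the same 3 arrays, so this gives no independent support. Contractile genes may move with ACTG2 and CCN1 in the USP22 shRNA array, and the list stood at percentile 100 there. Immediate early genes may be higher in both knockdown arrays, as DUSP5 and TRIB1 were, and the list stood at percentile 100 in each; since both comparisons share the control array, a lower level in that culture stays open. Over 5 other background and scaling settings these 3 lists kept those percentiles. Complex I genes were predicted to fall below percentile 2.5 with USP22 shRNA, opposite to hypoxia genes, and did not, at 2.92; over those 5 settings the percentile ran from 1.55 to 2.92.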
